A study of Homo sapiens with 10 samples.

How the data were processed

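The series profiled A549 cells, a human lung adenocarcinoma line, with single-colour (Cy3) Agilent whole human genome expression arrays. Per the labels, stable lines carried pSuper Retro Puro with an empty insert (shVector) or a hairpin against SMAD2 or SMAD3, or pSin EF2 Puro empty (Vector) or with CCT6A. Cells were infected with 2.5 µg/mL polybrene, selected for 10 days in 1.5 µg/mL puromycin, kept in 10% fetal bovine serum, and given vehicle or TGF-β1 for 12 h. The authors deposited 10 files, 1 per line and treatment, so no line had a replicate of the same treatment. Nothing in the labels says that arrays came from separately derived cultures, so p-values measure only the spread between these arrays.

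Per the file headers, the scanner software was Feature Extraction 10.7.3.1 with protocol GE1 107_Sep09. The processed signal of each spot is an intensity per the file headers, background subtracted and detrended on each array and not scaled between arrays. Each file held 45015 spots, of which 1639 were controls and 43376 measured 41000 probes. Probe positions were on GRCh37. The deposited series table is on the log2 scale and holds 41093 probes, of which 41000 matched the scanner files. Its scale, centring and direction were not stated and were found by comparison with the scanner files. Differences between its columns followed log2 differences of the processed signal with a slope of 1.00 and a Pearson r of 0.9997 to 0.9999 across probes, and the median of every probe over the 10 columns was 0. The column medians were -0.06 (shVector vehicle), -0.04 (shVector TGF-β1), 0.08 (shSMAD2 vehicle), 0.02 (shSMAD2 TGF-β1), 0.01 (shSMAD3 vehicle), 0.11 (shSMAD3 TGF-β1), -0.06 (Vector vehicle), -0.05 (Vector TGF-β1), 0.01 (CCT6A vehicle) and 0.04 (CCT6A TGF-β1). These values served as an alternative scaling.

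Both Vector files were copies of the shVector files of the same treatment. They gave the same slide, position and scan. Rounded to 3 significant digits, 45012 (vehicle) and 45014 (TGF-β1) of 45015 spots were equal, the largest relative difference was 0.495%, and quality flags and background values were equal at all 45015 spots. Between the shVector and shSMAD2 arrays the median relative difference was 23.8% (vehicle) and 15.7% (TGF-β1). Each pair of copies was averaged and counted as 1 array, called the control below, which left 8 arrays and 4 lines. The same arrays thus carry the labels of both empty vectors, pSuper and pSin, so 1 of these vectors was not measured. Differences of CCT6A, or of the hairpin lines, from the control may therefore mix the vector with the insert. The design chosen before the data were examined had used Vector as a separate line. That part was replaced: response differences were taken against the mean of the other 3 lines, and genes for the median response change were chosen on the mean response of the 2 lines not compared. The control and shSMAD2 arrays lay on slide 1 and the arrays labelled shSMAD3 and CCT6A on slide 2, so slide and line cannot be separated in comparisons across slides.

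Spots marked by the scanner software as outliers (36 to 61 per array) were left out, and no spot was saturated. The log2 processed signal minus the 75th percentile of its array was averaged over the spots of a probe. Probes well above background on at least 2 arrays were kept, and 1 probe per gene, that with the highest mean, was used. This gave 19104 genes, of which 13557 had a plain symbol in the RefSeq table used for names. That table matched 27294 of the 41000 probes by accession and held the symbol of 29677, and 83 probes with incomplete values were left out. Genes without a plain symbol were tested but not named, and XIST and Y-linked genes were left out of the text. Where a gene was not above background on any array of 1 side, its fold was computed against the higher of its signal and the lowest signal called well above background on that array, and is given as "at least", as it is for TGF-β1 folds of genes above background on 1 of the 4 arrays of 1 side.

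R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8) fitted line plus treatment to every gene (3 residual degrees of freedom, 1.90 prior). Line was thereby the block that paired vehicle with TGF-β1. The TGF-β1 effect and the 3 line contrasts came from this fit. Response differences added a treatment term for 1 line (2 residual degrees of freedom) or for both hairpin lines (1). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 96 tests of 24 lists in 4 contrasts. Lists with under 5 measured members were dropped, which removed the endothelial markers (1 measured member). Response changes of lists have no test. Their medians are given as percentiles among 10000 random lists of equal size matched on mean signal. These list changes were not signed by direction, so a falling member that fell more counts as lower. Median response changes over all responding genes carry 95% bootstrap intervals over genes (2000 draws) and were signed so that a smaller response is negative. A simulated effect of an array shared by 2 comparisons used 100 draws, or 20 sets of 8 arrays for the line contrasts.

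On simulated data with 19104 genes, the TGF-β1 test recovered 66% of genes changed 2-fold and 86% of genes changed 4-fold. The contrast of the line labelled shSMAD3 with the control recovered 43% and 81%, and the response difference of shSMAD2 0% and 0%. A planted median response change of -0.50 was recovered as -0.47. A list shifted by 1 on the log2 scale gave a camera p of 1.29e-56 with the preset and 0.00126 with an estimated correlation, and an unshifted list gave 0.816 and 0.865.

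Before the data were examined, the lists, the rules for naming genes, the tests and most alternatives were fixed. Named genes were the 3 targets, the 12 largest rises and 12 largest falls under TGF-β1 (3 of the rises are not reported here), the 6 largest in each direction for each line contrast and response difference, and the members of a list with the largest changes past the threshold, or of all measured members where none passed. Where no response difference passed, the largest changes against the control were given without a test, genes above background on all 4 arrays of the 2 lines first. Members named because they ran against their list, or to complete a count of 5 or fewer, were chosen after their values were seen. Alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization alone, the deposited table, no filter on dim probes, probes above background on all arrays, the mean of all probes of a gene, trend and robust variance moderation, an estimated correlation, no block, other fold minimums (1.5 and 3) and leaving out each line or array. Added after seeing the data were each slide alone, the 10 files counted as separate samples, and genes for the median response change chosen in the control or in single lines. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays limits the precision of every value.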

Results

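Transcript levels were measured in A549 lung adenocarcinoma cells that carried hairpins against SMAD2 or SMAD3, the transcription factors that act directly below the TGF-β receptors, or extra CCT6A, a subunit of the TRiC/CCT chaperonin that folds cytosolic proteins. Each line received vehicle or TGF-β1 for 12 h. The 10 files held 8 distinct arrays, because both files labelled Vector repeated the shVector arrays of the same treatment, differing by at most 0.495% at any spot, and each pair was counted as 1 sample. This left 4 lines with 2 arrays each (vehicle and TGF-β1): the control, shSMAD2, the line labelled shSMAD3, and CCT6A. Between 59.6% and 64.2% of spots were well above background on each array, and the 75th percentile of the processed signal ranged from 954 to 1307. There were no replicates of a line and treatment, so the number of arrays limits the precision of each value.

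The targets of the constructs were read first. SMAD2 was lower in the shSMAD2 line than in the control at all 4 probes, with a mean log2 difference of -0.90 at the probe used (chromosome 18, 45368031 to 45368090 of GRCh37, minus strand), or 53.7% of the control signal. The other SMAD2 probes gave 61.6%, 55.1% and 46.0%. SMAD3 was not lower in the line labelled shSMAD3: the probe used (chromosome 15, 67487391 to 67487450, plus strand) differed from the control by 0.07 and the second probe by 0.07, or 105% of the control at each. The same line had less SMAD2 signal at 2 of the 4 SMAD2 probes, with differences of -0.45 (73.4% of the control) and -0.51 (70.2%), while the dimmer probes gave -0.10 and 0.05. CCT6A was higher in the CCT6A line by 0.45 at the probe used (chromosome 7, 56130749 to 56130808, plus strand), or 136% of the control, and by 0.30 (123%) at the second probe. With quantile normalization the first of these was 0.31, and with normexp added 0.28. None of these differences passed the threshold in limma (adjusted p = 0.135 for SMAD2 in shSMAD2, 0.082 for SMAD2 in the line labelled shSMAD3 and 0.066 for CCT6A). CCT6A signal also lay above the control in shSMAD2 (111% at the probe used and 108% at the second) and in the line labelled shSMAD3 (110% at each). At the second probe under TGF-β1 the difference was 0.20 in CCT6A, 0.20 in shSMAD2 and 0.22 in the line labelled shSMAD3.

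**Figure D1:**
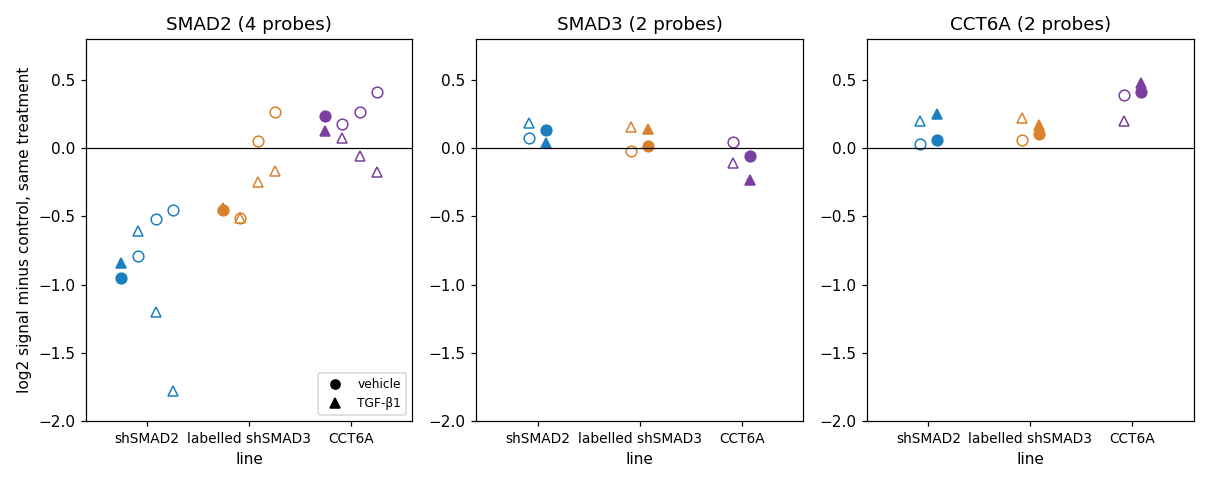
Log2 signal of SMAD2, SMAD3 and CCT6A probes in each line minus the control array of the same treatment. Circles are vehicle and triangles TGF-β1 arrays, 1 array each, and filled symbols mark the probe used for the gene. SMAD2 lies below the control in shSMAD2 (mean -0.90 at the probe used), and SMAD3 lies near 0 in the line labelled shSMAD3 (0.07).

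The first comparison asked what TGF-β1 did to A549 cells over the 4 lines. Matrix genes were among the largest rises. COL1A1, a chain of type I collagen, rose by 6.28 ± 0.19 on the log2 scale (SE, n = 4 lines; 77.5-fold; probe at chromosome 17, 48261565 to 48261626), and CGB3, a chorionic gonadotropin subunit gene, rose 58.1-fold. The other genes named from the 12 largest rises were the proteoglycan gene SPOCK1 (53.3-fold), the hyaluronan-binding TNFAIP6 (51.2-fold), PLEK2 (48.3-fold), the metalloproteinase gene ADAM19 (47.7-fold), BEAN1 (5.36 on the log2 scale), the smooth muscle calponin gene CNN1 (at least 4.39 on the log2 scale) and NPTX1 (34.8-fold). Of the genes that fell, SCARA5, a scavenger receptor that takes up ferritin, fell by 5.45 ± 0.10, the most (43.8-fold lower; chromosome 8, 27727875 to 27727934). SLC51B, a subunit of a bile acid and steroid exporter, was at least 23.4-fold lower and TSPAN8 at least 12.5-fold lower, AGR2, a disulfide isomerase of mucus-secreting cells, 16.4-fold lower, and the asialoglycoprotein receptor gene ASGR1 13.9-fold lower. TM4SF20 was 12.9-fold lower, the mucin gene MUC5AC 12.0-fold, GDA at least 6.17-fold and ANXA13 10.8-fold lower, and the brush border myosin gene MYO1A fell by 3.46. The epithelial ETS factor genes EHF and SPDEF were 12.4-fold and 10.9-fold lower. Adjusted p in limma for these 21 genes lay between 0.000266 and 0.0018.

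**Figure D2:**
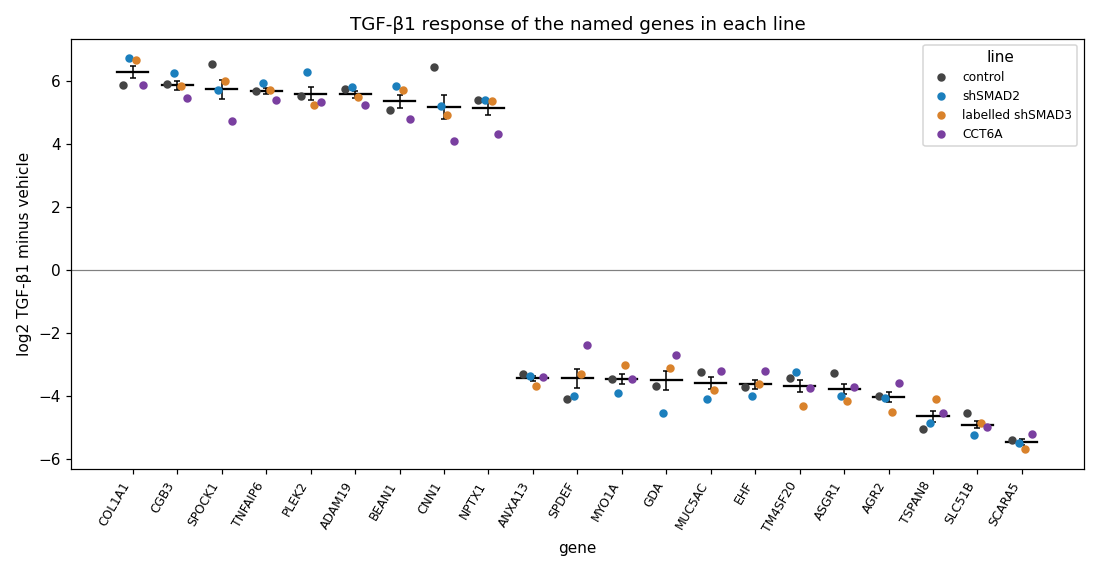
Log2 TGF-β1 minus vehicle signal of 9 of the 12 largest rises and of the 12 largest falls, 1 point per line, with the mean over the 4 lines as a bar and its limma SE as a whisker. All 21 genes moved in the same direction in all 4 lines, from 6.28 for COL1A1 to -5.45 for SCARA5.

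Genes of the matrix, of its remodelling and of SMAD signalling rose as groups. Of 24 measured direct TGF-β/SMAD targets, 21 rose and 0 fell (median 1.81), with CCN2, a matricellular growth regulator, at 3.33, JUNB, a subunit of AP-1, at 2.92, and LDLRAD4, a membrane inhibitor of SMAD signalling, at least 8.50-fold higher. The camera adjusted p was 1.65e-12 with the preset and the adjusted p = 0.625 with an estimated correlation, and 22 members passed when adjusted over the list alone. Of 26 matrix remodelling enzymes and inhibitors, 23 rose (median 2.05, or 1.63 with 6 dim members at their bounds). Examples were ADAM19 (5.57), the metalloproteinase inhibitor gene TIMP3 (at least 7.19-fold) and the metalloproteinase gene MMP10 (at least 6.55-fold). Only MMP7 fell, by 0.87 (adjusted p 3.35e-13, adjusted p = 0.697 with an estimated correlation, 24 adjusted over the list alone). Of 25 collagens and matrix proteins, 18 rose (median 1.66, or 1.32 with 1 dim member at its bound), among them COL1A1, SPOCK1 and COL5A1 (4.84), and LAMA3 fell by 1.14 (adjusted p 6.46e-08, adjusted p = 0.625 with an estimated correlation, 19 adjusted over the list alone). Of 12 integrins, which bind cells to the matrix, 10 rose (median 1.46), led by ITGA11 (3.41), ITGB4 (1.96), ITGA5 (1.81) and ITGB3 (at least 1.68-fold), and ITGB5 fell by 0.66 (adjusted p 8.43e-05, adjusted p = 0.625 with an estimated correlation, 11 adjusted over the list alone).

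Of 21 prometastatic TGF-β targets, 16 rose (median 1.85, or 1.83 with 2 dim members at their bounds). Examples were the ligand gene WNT5B (at least 21.5-fold higher), the growth factor gene PDGFB (4.66), the interleukin gene IL11 (4.58) and ANGPTL4, an inhibitor of lipoprotein lipase (4.52). VEGFC fell by 0.89 (adjusted p 6.46e-08, adjusted p = 0.625 with an estimated correlation, 18 adjusted over the list alone). Of 18 mesenchymal genes, 11 rose (median 0.86), with CNN1 in front, the matricellular SPARC at least 9.12-fold higher, the cadherin gene CDH11 at 3.49 and TAGLN, an actin-binding protein of smooth muscle, at 3.48, and TWIST2 fell by 0.58 (adjusted p 2.47e-05, adjusted p = 0.76 with an estimated correlation, 13 adjusted over the list alone). The epithelial list moved both ways: 5 of 24 rose and 10 fell (median -0.27, adjusted p 0.121, adjusted p = 0.76 with an estimated correlation, 15 adjusted over the list alone). The tight junction gene CLDN4 rose by 4.06, whereas E-cadherin (CDH1) fell by 2.73, the epithelial factor gene ELF3 by 2.06 and the junction gene TJP3 was at least 3.49-fold lower.

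NRF2 target genes, which serve glutathione and NADPH supply, fell as a group: 18 of 21 fell (median -0.86, adjusted p 3e-07, adjusted p = 0.625 with an estimated correlation, 19 adjusted over the list alone). The largest falls were the glutathione peroxidase gene GPX2 (-3.01), OSGIN1 (-2.07), the aldehyde dehydrogenase gene ALDH3A1 (-1.94) and the exporter gene ABCC2 (-1.84), and the heme oxygenase gene HMOX1 rose by 0.49. Of 20 NF-κB and inflammatory genes, 12 fell and 4 rose (median -0.95, or -0.67 with 3 dim members at their bounds; adjusted p 0.00685, adjusted p = 0.878 with an estimated correlation, 17 adjusted over the list alone). The chemokine gene CCL20 was at least 7.36-fold lower, the neutrophil chemokine gene CXCL5 fell by 2.41 and the prostaglandin synthase gene PTGS2 by 2.16. The 4 that rose were CCL2, RELB, NFKB2 and NFKB1. With all arrays required above background the NF-κB list no longer passed (adjusted p 0.0596).

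The receptor and SMAD genes split. TGFBR1 rose by 2.47, BMPR2 by 1.96 and the inhibitory SMAD7 by 1.92, while TGFBR3 was at least 2.66-fold lower (4 of 16 rose, 3 fell; adjusted p 0.654, adjusted p = 0.967 with an estimated correlation, 9 adjusted over the list alone). ID and BMP-type targets also split, with HEY1 up by 2.72, ID4 and ID2 down by 1.34 and 1.29, and ATOH8 at least 3.95-fold lower (3 of 11 rose, 3 fell; adjusted p 0.88, adjusted p = 0.968 with an estimated correlation, 6 adjusted over the list alone). Among antimetastatic or growth suppressing genes 8 of 24 rose, with TIMP3, IGFBP7 (3.35) and the proapoptotic BMF (1.89) in front, and 7 fell, CDH1 the most (adjusted p 0.654, adjusted p = 0.967 with an estimated correlation, 16 adjusted over the list alone). Among hypoxia and glycolysis genes VEGFA rose by 2.53 and the glucose transporter gene SLC2A1 by 1.77, whereas CA9 fell by 1.65 and ADM by 1.56 (7 of 22 rose, 8 fell; adjusted p 0.933, adjusted p = 0.968 with an estimated correlation, 18 adjusted over the list alone). Of 18 p53 targets 7 rose, with TP53I3 at 2.42 and the cell cycle inhibitor gene CDKN1A at 1.12, and 2 fell, GDF15 by 1.75 and FDXR by 0.56 (adjusted p 0.116, adjusted p = 0.878 with an estimated correlation, 10 adjusted over the list alone). Of 27 proliferation genes 0 rose and 5 fell, namely PCNA, AURKA, CCNB1, CCNA2 and E2F1, each by 0.27 to 0.53 (list median -0.18, adjusted p 0.0597, adjusted p = 0.967 with an estimated correlation, 3 adjusted over the list alone).

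Chaperone, sterol and stress genes moved little or both ways under TGF-β1. Of 13 heat shock genes 2 rose and 5 fell, with the small heat shock gene HSPB1 at 1.74 and HSPA1A at -0.65 (adjusted p 0.785, adjusted p = 0.967 with an estimated correlation, 7 adjusted over the list alone). Of 15 chaperonin and prefoldin genes 0 rose and 5 fell, with CCT6B at -0.54 and TCP1 at -0.33 (adjusted p 0.477, adjusted p = 0.967 with an estimated correlation, 6 adjusted over the list alone). Of 17 cholesterol synthesis genes 2 rose and 4 fell, with STARD4 at 0.83 and HMGCS1 at -0.53 (adjusted p 0.389, adjusted p = 0.967 with an estimated correlation, 9 adjusted over the list alone). Of 18 ER stress and amino acid response genes 5 rose and 4 fell, with XBP1 at -0.82 and the ER chaperone gene HSPA5 at 0.77 (adjusted p 0.654, adjusted p = 0.967 with an estimated correlation, 10 adjusted over the list alone). Of 15 interferon response genes 4 rose and 6 fell, with IFIT2 at least 2.52-fold lower and OASL at 1.02 (adjusted p 0.788, adjusted p = 0.967 with an estimated correlation, 12 adjusted over the list alone). Among 12 alveolar epithelial genes LPCAT1 and GATA6 rose by 0.77 and 0.68 and FOXA2 fell by 0.92 (adjusted p 0.766, adjusted p = 0.967 with an estimated correlation, 3 adjusted over the list alone). Of 5 fibroblast markers COL1A1 and PDGFRA rose (adjusted p 0.254, adjusted p = 0.878 with an estimated correlation, 2 adjusted over the list alone), and of 6 haematopoietic markers 2 rose and 3 fell, with ITGAM at -1.25 and CD14 at -0.80 (adjusted p 0.886, adjusted p = 0.968 with an estimated correlation, 5 adjusted over the list alone). Of 7 neural and renal lineage genes LHX1 rose by 0.86 and INA fell by 0.53 (adjusted p 0.933, adjusted p = 0.968 with an estimated correlation, 2 adjusted over the list alone). Of the endothelial markers only ESAM was measured (2.87).

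In limma, 6166 of 19104 genes passed the threshold for TGF-β1, 2807 up and 3359 down, of which 946 rose and 726 fell by at least 2-fold, and 653 genes rose and 440 fell by at least 2-fold in all 4 lines. Of the called genes 45.5% rose, and the median of all genes was -0.05. Without line as the block that pairs the arrays, 4226 genes passed. Within slide 1 (control and shSMAD2) 1121 genes passed, 1089 of them also in the full comparison, and within slide 2 the numbers were 1423 and 1357. Leaving out the shSMAD2 line gave 4035 genes and leaving out the line labelled shSMAD3 gave 3857. Of 1944 called genes with more than 1 probe, 116 had a probe whose mean response had the other sign.

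The line contrasts compared each line with the control, with treatment held constant. No line had a replicate, so p-values and SE measure only the spread between arrays. They cannot tell a construct from other differences between the lines. The vector is among these differences, since both empty-vector labels shared the same arrays. In the shSMAD2 line 4 genes passed. The cell surface adhesion genes CEACAM7 and CEACAM6 were lower by -3.62 ± 0.09 and -3.57 ± 0.19 (SE, limma adjusted p 0.0042 and 0.0481), the coagulation factor gene F5 by -1.64 ± 0.08, and HPD, an enzyme of tyrosine breakdown, was higher by 1.87 ± 0.10 (adjusted p 0.0481 for both). All 4 genes were also shifted in the same direction, past the threshold, in the line labelled shSMAD3 and in CCT6A. These contrasts share the control arrays, so the agreement may come from the control. No list member passed on its own. The epithelial list lay lower (median -0.26, adjusted p 0.000264, adjusted p = 0.625 with an estimated correlation, 2 adjusted over the list alone), with KRT19 at -3.41 and CLDN4 at -1.39. The integrins lay lower (median -0.21, adjusted p 0.00193, adjusted p = 0.625 with an estimated correlation, 3 adjusted over the list alone), with ITGB4 at -1.07. So did the alveolar epithelial genes (median -0.13, adjusted p 0.0492, adjusted p = 0.76 with an estimated correlation, 1 adjusted over the list alone; not past with quantile normalization, adjusted p 0.0685) and 7 neural and renal lineage genes (median -0.37, adjusted p 0.0114, adjusted p = 0.878 with an estimated correlation, 4 adjusted over the list alone), with NEFL at -1.03. Proliferation genes lay higher (median 0.25, adjusted p 0.00105, adjusted p = 0.882 with an estimated correlation, 0 adjusted over the list alone), as did the chaperonin and prefoldin genes (median 0.15, adjusted p 0.0266, adjusted p = 0.878 with an estimated correlation, 0 adjusted over the list alone; adjusted p 0.462 with quantile normalization). At an unadjusted p under 0.05 there were 3340 genes. Leaving out any 1 of the 4 arrays compared left 0 genes in limma, with 1883 to 2655 at an unadjusted p under 0.05.

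In the line labelled shSMAD3, 514 genes passed, 337 up and 177 down. The imprinted noncoding H19 was higher by 2.25 ± 0.22 (SE), HPD by 2.24, GCM1, a placental transcription factor gene, by 2.11, DUSP13A by 2.08, and the elastic fibre gene ELN by 1.99, and EFEMP1, a fibulin gene, also rose. For GCM1 and ELN the probes of the gene gave TGF-β1 responses of different sign. MAPK4 was lower by -3.28 ± 0.45, CEACAM6 by -2.97, CEACAM7 by -2.89, DNAJC15, a mitochondrial cochaperone gene, by -2.63, CEMIP, a hyaluronan-degrading protein gene, by -2.42 and PRR15 by -2.13. DNAJC15 was above background on 1 of the 4 TGF-β1 arrays. Adjusted p for these 12 genes lay between 0.0127 and 0.045. Of 18 mesenchymal genes 3 rose, SPARC by 1.77, TAGLN by 1.33 and SNAI1 by 1.06, without a shift of the list (adjusted p 0.654, adjusted p = 0.967 with an estimated correlation, 9 adjusted over the list alone). Of 24 epithelial genes 2 fell, OVOL2 by 1.47 and CLDN2 by 1.17 (median -0.20, adjusted p 0.00731, adjusted p = 0.625 with an estimated correlation, 4 adjusted over the list alone). Of 12 integrins 2 fell, ITGB4 by 1.48 and ITGA6 by 0.75 (median -0.14, adjusted p 0.0365, adjusted p = 0.76 with an estimated correlation, 3 adjusted over the list alone; adjusted p 0.072 with quantile normalization). Of 27 proliferation genes 0 passed (median 0.18, adjusted p 0.0482, adjusted p = 0.967 with an estimated correlation, 0 adjusted over the list alone), and the median was -0.03 without the control TGF-β1 array. The share of called genes that rose was 65.6%, but 37.0% with normexp and quantile normalization and 41.1% with quantile normalization alone. Leaving out any 1 of the 4 arrays compared left 0 genes in limma, with 2646 to 4132 at an unadjusted p under 0.05.

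The CCT6A line had 503 genes past the threshold, 315 up and 188 down. BCAT1, which starts the breakdown of branched-chain amino acids, was higher by 2.26 ± 0.17 (SE), SEZ6 by 2.06, LYZL1 by 1.91, the testis antigen genes SPANXD and SPANXA1 by 1.91 and 1.90, and EFEMP1 by 1.75. CEACAM6 was lower by -3.20 ± 0.19, CEACAM7 by -3.13, the mucus protein genes FCGBP and MUC5AC by -2.72 and -2.62, TSPAN8 by -2.49 and DNAJC15 by -2.26. The last 2 were above background on 1 of the 4 TGF-β1 arrays. Adjusted p for these 12 genes lay between 0.00829 and 0.0487. Proliferation genes were higher as a group: only CDC6, a DNA replication licensing gene, rose over all genes tested (0.69), while 19 of 27 passed adjusted over the list alone (median 0.44, adjusted p 3e-07, adjusted p = 0.878 with an estimated correlation). The 15 chaperonin and prefoldin genes lay higher with CCT6A itself among them (median 0.37, adjusted p 0.000905, adjusted p = 0.76 with an estimated correlation). None of them passed over all genes and 11 passed adjusted over the list alone, with PFDN4 at 0.66 and CCT7 at 0.52. The list median was 0.23 with normexp and quantile normalization and 0.24 with quantile normalization alone. Under the main scaling the brightest genes of all lay higher in CCT6A than in the control. Their median distance from the mean of the 4 lines was 0.11 against -0.05 under vehicle and 0.04 against -0.10 under TGF-β1. The heat shock genes lay higher (median 0.32, adjusted p 0.0087, adjusted p = 0.76 with an estimated correlation, 6 adjusted over the list alone), but not past the threshold with normexp or quantile normalization (adjusted p 0.214 and 0.169). Of 17 cholesterol synthesis genes 2 rose, IDI1 by 0.72 and SQLE by 0.56 (median 0.28, adjusted p 0.0087, adjusted p = 0.878 with an estimated correlation, 4 adjusted over the list alone).

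Of 24 epithelial genes 4 fell in the CCT6A line, OVOL2 by 1.28, the junction plakoglobin gene JUP by 1.06, EPCAM by 0.64 and DSP by 0.63 (median -0.46, adjusted p 0.00208, adjusted p = 0.625 with an estimated correlation, 11 adjusted over the list alone). Of 12 integrins ITGB4 fell by 1.19 (median -0.41, adjusted p 0.00208, adjusted p = 0.625 with an estimated correlation, 3 adjusted over the list alone). Of 20 NF-κB and inflammatory genes the iron-binding LCN2 fell by 1.72 (median -0.16, adjusted p 0.00398, adjusted p = 0.878 with an estimated correlation, 5 adjusted over the list alone). Among matrix genes ELN rose by 1.47 while LAMB3, FN1 and COL4A4 fell by 1.47, 1.40 and 0.88, with no shift of the list (adjusted p 0.398, adjusted p = 0.967 with an estimated correlation, 9 adjusted over the list alone). The amino acid synthesis genes PSAT1 and ASNS rose by 1.30 and 1.12 (list adjusted p 0.0804, adjusted p = 0.878 with an estimated correlation, 8 adjusted over the list alone), and the growth suppressing BMF and MTSS1 fell, to at least 1.92-fold and 1.62-fold lower (list adjusted p 0.15, adjusted p = 0.882 with an estimated correlation, 5 adjusted over the list alone). Of the called genes 62.6% rose, against 54.0% with normexp and quantile normalization and 56.7% with quantile normalization alone. Leaving out the CCT6A vehicle array left 7 genes, and leaving out any other of the 4 arrays compared left 0 in limma, with 3327 to 4631 at an unadjusted p under 0.05.

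**Figure D3:**
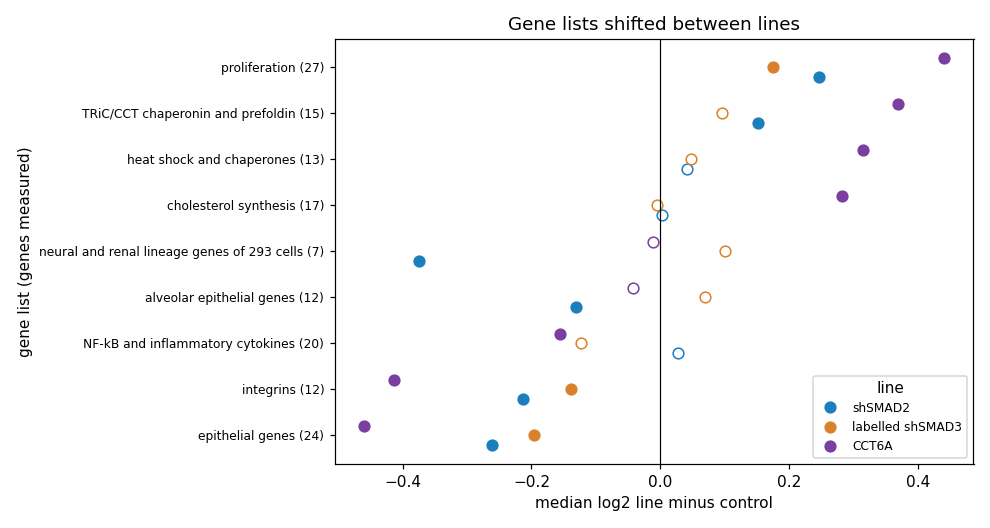
Median log2 difference of each line from the control over the members of each gene list that shifted in at least 1 line. Filled circles mark an adjusted p under 0.05 in camera with the preset correlation, and no list passed with an estimated correlation. Proliferation genes lie highest in CCT6A (0.44), and epithelial genes lie below 0 in the 3 lines (-0.26, -0.20 and -0.46).

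The contrasts of the line labelled shSMAD3 and of CCT6A shared 249 called genes, 248 of them in the same direction (194 up, 54 down), against 5.56 up and 1.74 down for independent sets. Both contrasts used the same control arrays, which could not be split. Simulated arrays with no line effect gave an overlap of 0, a correlation across genes of 0.496 and a covariance of 0.0313, against 0.429 and 0.0962 in the data. Part of the covariance may thus come from noise in the shared control, but that noise alone gave no overlap. A control line set apart from the others was not part of this simulation. In the 248 genes the median shift, signed by the shared direction, was 1.08 in the line labelled shSMAD3, 1.09 in CCT6A and 0.37 in shSMAD2. Without the filter on dim probes the median of all genes shifted by 0.12 in shSMAD2, 0.19 in the line labelled shSMAD3 and 0.13 in CCT6A. These comparisons also lay across slides, since the control was on slide 1 and both lines on slide 2. Among lists, proliferation genes lay above the control in shSMAD2, the line labelled shSMAD3 and CCT6A (0.25, 0.18 and 0.44). Epithelial genes (-0.26, -0.20 and -0.46) and integrins (-0.21, -0.14 and -0.41) lay below it in the same lines. The part of these shifts common to the lines cannot be told apart from a control set apart from them.

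The last comparison asked whether the TGF-β1 response itself depended on the construct. The CCT6A line had the smallest response of the 4 lines in 497 of the 946 genes (52.5%) that rose at least 2-fold. For the genes that rose at least 2-fold the median response was 1.51 in CCT6A, 1.78 in the control, 1.83 in shSMAD2 and 1.75 in the line labelled shSMAD3. A smaller response can come from a higher vehicle signal as well as from a lower TGF-β1 signal, and these were not separated. For the genes that fell at least 2-fold CCT6A also had the smallest response in 292 of 726 (40.2%), with a median of -1.43 against -1.52 in the control, but genes chosen on the lines not compared fell more in CCT6A than in the control (median change 0.18), so for falling genes the direction turned with the choice of genes. Among gene lists that rose, several had lower TGF-β1 minus vehicle differences in CCT6A than in the control. These differences were not signed by direction, so a falling member that fell more counts as lower. They were lower for 23 of 26 matrix remodelling genes (median change -0.37, percentile 0 among random lists). The same held for 19 of 25 collagens and matrix proteins (-0.30, percentile 0), although the median response itself was 1.40 in CCT6A and 1.33 in the control. It also held for 15 of 21 prometastatic targets (-0.37, percentile 0.01) and 17 of 24 direct targets (-0.18, percentile 0.15). Integrins were lower in 8 of 12 genes (-0.19, percentile 1.21) and changed as much in the line labelled shSMAD3 (-0.20, percentile 0.52). Collagens and matrix proteins also changed by -0.17 in the line labelled shSMAD3 (percentile 0.34) and by -0.08 in shSMAD2 (percentile 2.67). With normexp and quantile normalization these changes were 0.05 and -0.06. The mesenchymal genes, which also rose, split evenly in CCT6A (9 of 18 lower, median change -0.0077, percentile 68.6, and 0.10 with normexp and quantile normalization). Quantile normalization gave -0.17 for the remodelling genes and kept the other lists with lower differences in CCT6A below 0. The random lists were matched on signal and not on response, and rising genes as a whole had a median change of -0.23 in CCT6A, so these lists are not shown to differ from other rising genes. CCN2 ran against its list, with responses of 4.21 in CCT6A and 2.39 in the control.

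Direct SMAD targets had a median response of 1.61 in the control, 1.75 in shSMAD2 and 2.05 in the line labelled shSMAD3, with median changes of 0.23 (percentile 99.6) and 0.19 (percentile 98.8), positive under each scaling tried but 0.13 and 0.10 with normexp and quantile normalization. ID and BMP-type targets had higher TGF-β1 minus vehicle differences than in the control in 10 of 11 genes in shSMAD2 (median change 0.54) and in 9 of 11 in the line labelled shSMAD3 (0.46), or 0.35 and 0.32 with normexp and quantile normalization. Their median response was 0.04 in the control, -0.06 in shSMAD2 and 0.03 in the line labelled shSMAD3. NF-κB and inflammatory genes, whether they rose or fell under TGF-β1, had higher differences than in the control in 20 of 20 genes in shSMAD2 (median change 0.28) and in 17 of 20 in the line labelled shSMAD3 (0.27). Proliferation genes had a median response of -0.42 in the control and -0.05, -0.18 and -0.07 in shSMAD2, the line labelled shSMAD3 and CCT6A, and 26, 27 and 25 of 27 genes lay above their control response. Mesenchymal genes had higher differences than in the control in 15 of 18 genes in the line labelled shSMAD3 (median change 0.27). In shSMAD2 this held for 12 of 18 genes (0.18). All changes in this paragraph were taken from the same control arrays, 1 per treatment, and were not tested. A control set apart from the other lines cannot be told apart here from an action of the hairpins. The random lists were matched on signal and not on response.

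**Figure D4:**
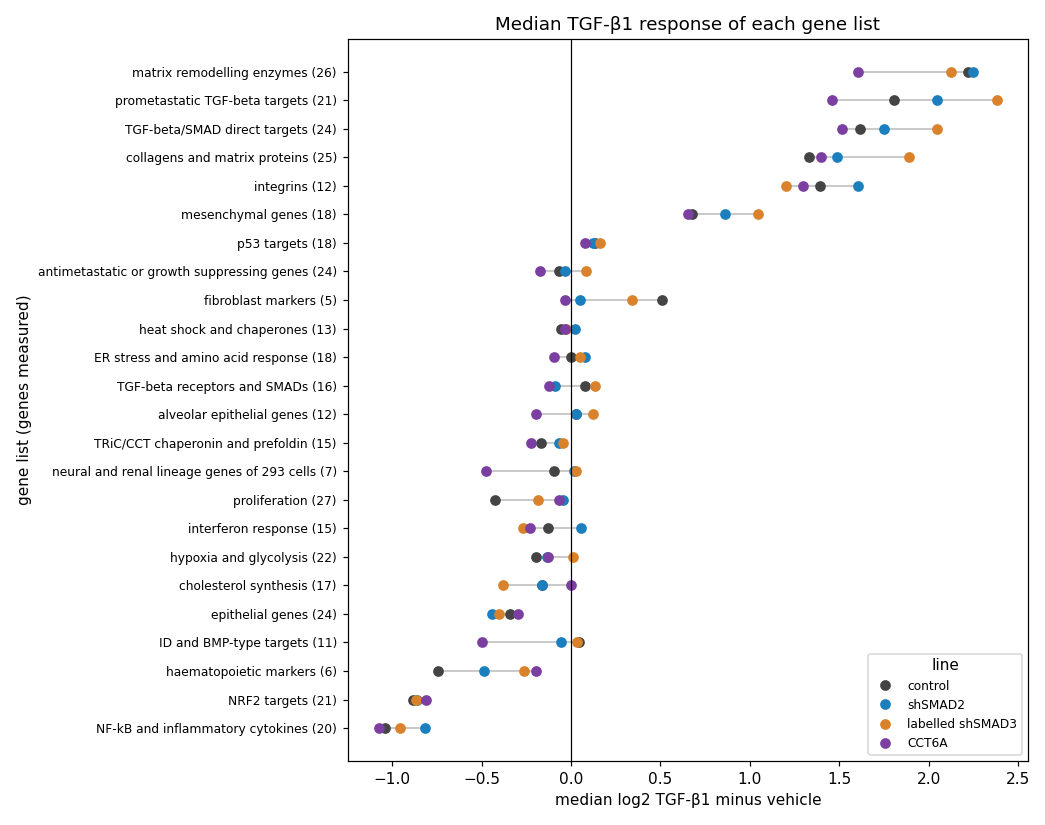
Median log2 TGF-β1 minus vehicle signal over the measured members of each gene list, 1 point per line. Matrix remodelling genes lie lowest in CCT6A (1.61) and between 2.12 and 2.25 in the other lines, and proliferation genes lie lowest in the control (-0.42).

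No single gene passed the threshold for a response difference in limma. The counts were 0 for shSMAD2, the line labelled shSMAD3 and CCT6A, each against the mean of the other 3 lines, and 0 for the line labelled shSMAD3 minus shSMAD2. At an unadjusted p under 0.05 there were 760, 694, 794 and 785 genes, and the smallest adjusted p values were 0.641, 0.912, 0.143 and 0.999. With normexp and quantile normalization 4 genes passed for CCT6A. The test was simulated for shSMAD2 only and recovered 0% of 4-fold differences, so its count does not exclude differences of that size. The other comparisons, with as many or fewer residual degrees of freedom, were not simulated. The largest response changes against the control therefore have no test, and were taken from genes well above background on all 4 arrays of the line and the control. In shSMAD2 they were CMTR1 (1.65), PITPNM1 (1.51), NPM3 (1.49), C21orf58 (1.46), SLITRK6 (1.46) and BTN3A3 (1.43), and CRHR1 (-3.89), ASAP1-IT1 (-3.49), ZBTB20 (-2.98), PAX4 (-2.78), INE1 (-2.58) and PRAC1 (-2.37). In the line labelled shSMAD3 they were OR51E2 (1.93), ZNF296 (1.78), FRMD4A (1.75), GNRH2 (1.66), TRIM5 (1.64) and IGFBP3 (1.56), and CRHR1 (-2.73), GUSBP3 (-2.54), SPDYE7P (-2.39), ASAP1-IT1 (-2.31), PAX4 (-2.14) and ZBTB20 (-2.11). With normexp and quantile normalization PAX4 was at -1.30 in shSMAD2 and ZNF296 at 0.83 in the line labelled shSMAD3. With the mean of all probes C21orf58 was at 0.58, TRIM5 at 0.73 and FRMD4A at -0.33, and the probes of PAX4 and TRIM5 gave responses of different sign. In CCT6A they were KRT19 (2.20), RHOV (1.94), CCN2 (1.82), GSTA2 (1.82), RGCC (1.71) and SPDEF (1.70), and CRHR1 (-3.73), IGLL5 (-2.92), TEKT5 (-2.89), ZNF91 (-2.89), CLDN4 (-2.73) and IRX3 (-2.70), with ZNF91 at -1.24 under normexp and quantile normalization. The epithelial keratin gene KRT19 had responses of 1.82 in CCT6A and -0.38 in the control, and CLDN4 had 1.43 and 4.16. CRHR1 appears in each line because the control stood apart, with a response of 4.05 against 0.16 in shSMAD2, 1.32 in the line labelled shSMAD3 and 0.32 in CCT6A.

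Over all responding genes the change was small. Signed so that a smaller response is negative, the median change was 0.09 in shSMAD2 (95% bootstrap interval 0.06 to 0.13, 1678 genes), 0.06 in the line labelled shSMAD3 (0.03 to 0.10, 1727 genes) and -0.06 in CCT6A (-0.09 to -0.04, 2243 genes). In CCT6A the genes that rose under TGF-β1 had a median of -0.23 and the genes that fell 0.18, a larger fall than in the control, unlike the genes chosen over all 4 lines. The larger fall was not particular to CCT6A: genes that fell had medians of 0.09 in shSMAD2 and 0.16 in the line labelled shSMAD3. Genes chosen in the control line itself gave -0.25 and -0.31 for the hairpin lines and -0.46 for CCT6A. The control response both chose these genes and was subtracted, which by itself pulls the values down. They therefore decide nothing about the direction. Across 19104 genes, which are not independent replicates, response changes against the control were correlated between lines: Pearson 0.75 and Spearman 0.65 for shSMAD2 with the line labelled shSMAD3, 0.62 and 0.50 for CCT6A with shSMAD2, and 0.58 and 0.46 for CCT6A with the line labelled shSMAD3. These 3 relations, computed also over the 6166 TGF-β1 genes (Pearson 0.63, 0.45 and 0.49), share the control arrays. The shared arrays alone gave a simulated Pearson of 0.50 and a covariance of 0.127, 0.126 and 0.127, against 0.350, 0.266 and 0.219 in the data, so part of the relations may come from the shared control. Over the TGF-β1 genes the covariances were 0.105, 0.0765 and 0.0876, against 0.0639, 0.0637 and 0.064 simulated.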

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

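All tests in this part were chosen after the results were seen, except the splits of the arrays, the comparison of proliferation genes across slides and that of the matrix lists without the control arrays.

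The TGF-β1 result was set against other splits of the 8 arrays into 4 and 4 with line in the model. Line pairs the arrays, so the real split compares with the 8 splits that part the treatments of all 4 lines, of which 1, the real one, gave 6166 genes or more, and the highest other count was 0. These 8 splits are too few for a share under 0.05. The other 24 splits that could be fitted part only 2 lines and leave the treatment in the spread, so their counts, at most 1, decide nothing.

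In the TGF-β1 responses of named genes, 1 line lay far from the other 3 in 1 case: NPTX1 rose by 4.33 in CCT6A and by 5.36 to 5.40 in the other lines. Its signal in CCT6A lay above the control by 1.43 under vehicle and still by 0.36 under TGF-β1. With 48 groups of 4 values tested, chance alone gives about 1 in 20, or 2.40.

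For 5 of 36 response changes named without a test, a line and the control moved at least 2-fold in opposite directions. In shSMAD2 these were ASAP1-IT1 (-1.86 against 1.63 in the control), ZBTB20 (-1.56 against 1.42) and PAX4 (-1.03 against 1.75). In the line labelled shSMAD3 it was SPDYE7P (-1.26 against 1.13), and in CCT6A it was IGLL5 (-1.09 against 1.82). In each of the 5 the control rose and the line fell. ASAP1-IT1, ZBTB20 and PAX4 were also among the largest negative response changes in the line labelled shSMAD3. For these genes the control may be the line set apart. Each rests on 1 array per treatment, and these differences were not tested.

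SMAD3 signal was not lower in the line labelled shSMAD3. An exchange of labels with another line of the series is argued against, since the lowest SMAD3 difference from the control in the other 2 lines was -0.15, and a failing single probe is argued against, since the second SMAD3 probe gave 0.068. A hairpin against SMAD2, or shSMAD2 cells, in this line stays open: 2 bright SMAD2 probes were lower (-0.45 and -0.51), but the least lowered SMAD2 probe was at 0.046, and the dimmer probes differed unevenly between treatments in shSMAD2 itself. A hairpin that acts on the protein without lowering the transcript, or one without effect, was not tested.

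The lines labelled shSMAD3 and CCT6A shared 248 genes past the threshold in the same direction. The slide as the whole cause is argued against, since shSMAD2, on the slide of the control, was shifted the same way by a median of 0.37 (0.33 to 0.42), against at most 0.06 from simulated control noise, and a control line set apart from the other 3 lines is a candidate explanation, since 91.5% of the genes were shifted the same way in shSMAD2 (simulated at most 66.2%). The excess over the shSMAD2 shift, a median of 0.71 (0.66 to 0.77), cannot be told apart from a slide difference, because both lines lay on slide 2. For the proliferation genes of CCT6A the slide alone is argued against, since they lay 0.28 (0.20 to 0.32) above the line labelled shSMAD3 on the same slide. The intervals in this paragraph are over genes, which vary together (estimated correlation 0.65 for the proliferation genes). They do not measure the spread between arrays or lines. No biological explanation was tested beyond the constructs named by the labels, which stay open.

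Response changes against the control were correlated between lines. For shSMAD2 and the line labelled shSMAD3, shared control arrays with equal spread in every line are argued against, since the lowest excess of the covariance over their bound was 0.0386 (interval 0.0335 to 0.0438), and dim or unnamed transcripts are argued against, since the correlation was 0.72 in bright named genes (simulated at most 0.522). For CCT6A with the other 2 lines, dim or unnamed transcripts may account for the relation, since the correlation was 0.47 in bright named genes, and shared control arrays stay open, with excesses of 0.0938 and 0.0592 over all genes but as low as -0.00608 (interval -0.0101 to -0.00095) in bright named genes. The lower differences of the matrix and TGF-β target lists in CCT6A do not rest on the control arrays alone. The CCT6A response, not signed by direction, lay below the mean of the lines labelled shSMAD2 and shSMAD3 by a median of -0.43 (-0.50 to -0.30, 71 of 89 genes). Those lines had median changes from the control of 0.20 and 0.08 (remodelling), 0.23 and 0.19 (direct targets), 0.12 and 0.11 (prometastatic), and -0.08 and -0.17 (collagens and matrix proteins). By the labels they also carried another vector than CCT6A, so vector and insert stay mixed. Rising genes as a whole changed by -0.23 in CCT6A, so these lists are not shown to differ from them. The intervals here are also over genes and do not measure the spread between arrays or lines. A common action of SMAD2 and SMAD3 hairpins was not tested.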

How the results depend on the processing

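The slide, separate-file and line-by-line gene choices below were added after the data were seen. Where no reason is given, the cause was not tested. The TGF-β1 effect stayed within 1.5 times its 6166 genes under every scaling and filter tried, with 4226 without the line block. It fell to 1121 genes on slide 1 and 1423 on slide 2, where 4 arrays each were used, and ranged from 3857 to 4720 when 1 line was left out.

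The line contrasts depended on the processing. With normexp and quantile normalization CCT6A had 976 genes. With quantile normalization the counts were 1 for shSMAD2, 236 for the line labelled shSMAD3 and 201 for CCT6A, and the deposited table gave 1 for shSMAD2. Without the filter on dim probes they were 1, 130 and 3, and with all arrays above background 10, 860 and 1740, with other numbers of genes tested by construction. Trend and robust moderation gave 35 for shSMAD2 and 2219 for CCT6A. Counting the 10 files as separate samples gave 1270, 3021 and 4898, where the copied control arrays count 2 times. Leaving out 1 array gave 0 to 0 genes for shSMAD2, 0 to 0 for the line labelled shSMAD3 and 0 to 7 for CCT6A, with fewer samples and the lone array assumed to vary like the others. Response differences stayed at 0 except in CCT6A, with 4 genes under normexp and quantile normalization, 1 with all arrays above background and 2 with trend and robust moderation.

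With an estimated correlation, 0 gene lists passed for TGF-β1, 0 for shSMAD2, 0 for the line labelled shSMAD3 and 0 for CCT6A, so all 24 list shifts ended. Each of the 24 was computed again under each other scaling and probe filter and with the mean of all probes. Of these values 130 stayed past the threshold and 14 kept only their direction. Lists were not computed again with trend and robust moderation or without the block. Of the values with an array or line left out 75 stayed, 20 kept only their direction and 1 reversed: the proliferation shift of the line labelled shSMAD3 ran from -0.033 without the control TGF-β1 array to 0.34 without the control vehicle array.

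The median response change of shSMAD2 was 0.029 with normexp and quantile normalization, 0.0051 for genes past the TGF-β1 threshold, -0.25 for genes chosen in the control, 0.17 for genes chosen in the line labelled shSMAD3 and 0.058 for genes chosen in CCT6A. For the line labelled shSMAD3 it was 0.13 with quantile normalization, 0.014 for genes changed at least 3-fold, 0.0072 for genes past the TGF-β1 threshold, -0.31 for genes chosen in the control, 0.20 for genes chosen in shSMAD2 and 0.0094 for genes chosen in CCT6A. For CCT6A it was -0.16 with normexp and quantile normalization, -0.026 at 1.5-fold, -0.17 at 3-fold, -0.46 for genes chosen in the control and -0.037 for genes chosen in shSMAD2. The values for genes chosen in the control are low by construction, since the control response was also subtracted. The relation of CCT6A with the line labelled shSMAD3 was 0.48 with normexp and quantile normalization, and that of shSMAD2 with the line labelled shSMAD3 was 0.64 without the filter.

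Counting each named gene once per setting, 369 tests stayed past the threshold and 50 kept only their direction under other settings, and 96 and 112 with arrays or lines left out. Counted the same way, 202 untested response changes stayed and 6 moved, and 27 target values stayed and 3 moved. Not run were the empty-vector lines alone (copies), slide as a block (aliased with line) and leaving out lines for the difference between the hairpin lines (no residual degrees of freedom). Between 59.6% and 64.2% of spots were well above background, which limits what was measured in dim genes.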
